A study of Mus musculus with 9 samples.

How the data were processed

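RNA-seq was measured in 9 libraries of dendritic cells sorted from the mouse thymus, 3 each of populations named CD301b, SIRPa and XCR1. The labels conflict on the cells: their source name says thymocytes and their cell type says thymic dendritic cells, and the cell type is used here. Per the labels' protocols, thymi of C57BL/6 mice were digested with collagenase D, stained and sorted on a FACS Aria II, RNA was isolated with a Qiagen RNeasy Micro kit, and libraries for a NextSeq instrument were made with a Clontech stranded kit for small amounts of total RNA. The gates and the number of cells sorted are not given in the sources used here.

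Per the labels' processing notes, the authors used FastQC, Trimmomatic, HISAT2, SAMtools, featureCounts from Subread and edgeR with the mouse genome build mm10. Versions, the annotation and the strand setting of the counting are not given there. The deposited count table holds raw read counts per gene, as whole numbers, for 55302 gene symbols in the 9 libraries. A second deposited table holds log2 CPM values of 22066 genes, of which 22020 (99.8%) carry a symbol. For the 21590 genes matched to the counts, and taking those with at least 100 counts in a library, its median difference from log2 CPM recomputed here was 0.07 to 0.19 per library, with a quartile range of at most 0.00438. That table was used for this comparison alone and not for tests.

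In the count table, 24 symbols had been turned into dates, so the genes could not be told. They held 0.125 to 0.187% of the counts of a library and were left out of library sizes and tests. Libraries held 20246092 to 25438864 counts in all, and 3 counts, the floor used for a count of 0, corresponded to 0.119 to 0.150 CPM per library on TMM-scaled library sizes. For a group whose libraries were all at 0, the floor was 3 counts over the whole group on the same scale, and the ratio of the other group's mean level to it was given as "at least". Where a group had 1 to 3 counts, the ratio was given with its exact 95% interval. Reads carried no stated molecular identifiers, so these intervals and floors cover counting error only.

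Genes were kept with edgeR's filterByExpr (minimum count 10), which left 15417. Library sizes were scaled by TMM, and the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest, two-sided) was run in 1 fit over all 9 libraries with the 3 populations as groups and no other term. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Each pair of populations was 1 comparison, and P values were adjusted by Benjamini-Hochberg over the 15417 genes of a comparison, with a threshold of 0.05. Levels are TMM-normalised CPM as mean ± SD over 3 libraries, and log2 fold changes are given ± SE from that fit. The design text speaks of 3 mice, while the titles number the CD301b libraries 1, 3 and 4 and the others 1 to 3. Whether libraries of different populations came from the same animals, or whether animals were pooled, is not stated, so P values measure the spread between these libraries.

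Chosen before the data were examined were the design, the alternatives, 26 gene lists and the rule for the genes named in the text. By that rule, Xcr1, Mgl2, Sirpa, Il4, Il13, Il4ra, Il13ra1, Il2rg and Stat6 are named in every comparison where measured. In each direction, it takes the 6 genes with the largest log2 fold change among those past the threshold with an absolute log2 fold change of at least 1, a mean of at least 5 CPM over the 6 libraries and no overlap between the groups. Predicted gene models and antigen receptor segments were left out there. From each list it takes up to 3 called genes with the smallest adjusted p and, where needed, the uncalled gene with the highest mean CPM. A gene named outside this rule is said to be so. In the comparisons with XCR1 and within lists, the text gives only some of the genes that the rule took. For 3 libraries against 3, chance alone gives no overlap in 10% of genes.

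The lists were: cDC1 identity, cDC2 identity, mature DC programme, IL-4 and IL-13 response, type I interferon response, MHC class II presentation, MHC class I presentation, cell cycle, chemokines and chemokine receptors, pattern recognition receptors, T cell costimulation and inhibition ligands, apoptotic cell uptake, cholesterol efflux and LXR targets, cholesterol synthesis, immediate early and dissociation genes, mitochondrially encoded genes, thymocyte and T cell, B cell, plasmacytoid DC, macrophage, monocyte, granulocyte, NK cell and innate lymphoid cell, thymic epithelium, stroma and endothelium, and erythroid and platelet. Each was tested against the other genes with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison. The same test with an estimated correlation and the rotation test fry, which asks whether a list's genes move on balance one way, were alternatives. Calls were also counted after adjustment over the list alone.

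Other alternatives were DESeq2's size factors, no filter on low counts, a stricter filter (10 CPM in at least 3 libraries), DESeq2's Wald test, limma-voom, a fit on only the 6 libraries compared, the replicate number as a block, leaving out mitochondrial and ribosomal RNA genes, and leaving out each library in turn. After the data had been seen, further alternatives left out the library of each population with the highest thymocyte marker level, took that level as a covariate, and left out each library of the population not compared. Other splits of the libraries into groups were also counted.

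The tests were checked on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. Apart from these changes, all libraries were drawn from the same mean and dispersion per gene. The simulation therefore does not cover populations that differ in many genes or in their spread. For CD301b against SIRPa, over 14613 genes, edgeR recovered 40% of the 2-fold and 60% of the 4-fold changes and called 3 unchanged genes. For CD301b against XCR1, over 14681 genes, it recovered 38% and 62% with 11 unchanged genes called. For SIRPa against XCR1, over 14644 genes, it recovered 45% and 58% with 9. In the same order of comparisons, limma-voom called 3, 7 and 10 unchanged genes. DESeq2, run on 15417 genes, called 28, 48 and 41 unchanged genes. It recovered 43 to 53% of the 2-fold and 63 to 67% of the 4-fold changes. Gene positions are those of GENCODE mouse release M21 on GRCm38, in which all 174 named genes had a position. Exons shared with other genes were counted in the same annotation.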

Results

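The data are gene-level read counts from 9 RNA-seq libraries of thymic dendritic cells from C57BL/6 mice 8 weeks of age. Dendritic cells present antigen to T cells, and in the thymus they display self-antigens to developing thymocytes. The 3 populations, with 3 libraries each, are named for surface proteins: XCR1, a chemokine receptor of type 1 conventional dendritic cells (cDC1), SIRPα, a receptor of type 2 conventional dendritic cells (cDC2), and CD301b, a C-type lectin encoded by Mgl2. The series title concerns type 2 cytokines and SIRPα-positive dendritic cells. Total counts were 25438864, 24685114 and 20246092 in CD301b replicates 1, 3 and 4. They were 20481629, 22007300 and 20786141 in SIRPa replicates 1 to 3, and 20782089, 22030933 and 20513674 in XCR1 replicates 1 to 3.

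Each population carried the transcript it was named for. Xcr1 (chromosome 9, 123852315 to 123862029, minus strand) stood at 766 ± 96.7 CPM (SD, n = 3 in each population) in XCR1, 9.61 ± 5.19 in SIRPa and 0.619 ± 0.403 in CD301b libraries. Mgl2 (chromosome 11, 70130329 to 70137550, plus strand) stood at 624 ± 58.2 CPM in CD301b, 23.2 ± 5.32 in SIRPa and 1.82 ± 0.508 in XCR1 libraries. Sirpa (chromosome 2, 129592835 to 129632228, plus strand) stood at 646 ± 53.7 CPM in CD301b, 774 ± 58.6 in SIRPa and 12.5 ± 3.06 in XCR1 libraries. Mgl2 has a close paralog in Clec10a, and whether reads were split between them is not given in the sources used here.

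**Figure D1:**
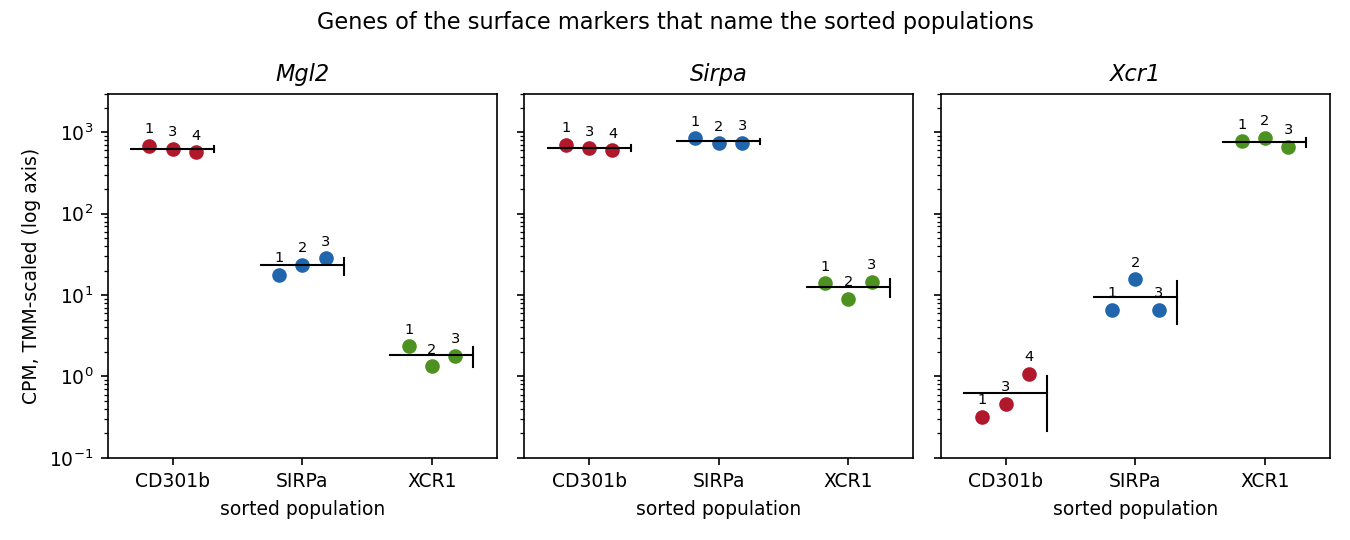
Level of Xcr1, Mgl2 and Sirpa in each library (CPM, log axis), with points numbered by replicate, lines for the mean and bars for the SD of 3 libraries. Xcr1 is highest in the XCR1 libraries, Mgl2 in the CD301b libraries, and Sirpa lies at 646 and 774 CPM in CD301b and SIRPa against 12.5 CPM in XCR1.

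CD301b and SIRPa libraries lay close to each other and apart from XCR1. Spearman correlations of log2 CPM were 0.951 to 0.962 between CD301b and SIRPa libraries, 0.889 to 0.913 between CD301b and XCR1, and 0.892 to 0.911 between SIRPa and XCR1. Within populations they were 0.958 to 0.969 for CD301b, 0.970 to 0.972 for SIRPa and 0.960 to 0.967 for XCR1. The first 3 principal components held 43.0%, 12.8% and 10% of the variance. On the first, XCR1 replicates 1 to 3 lay at 122, 129 and 92.6, and on the third, CD301b replicates 1, 3 and 4 lay at 58.4, 20.3 and -87.3. The summed level of thymocyte and T cell genes varied more between replicates than between populations, at 754 ± 337 CPM in CD301b, 757 ± 240 in SIRPa and 602 ± 484 in XCR1, with the highest value, 1157 CPM, in XCR1 replicate 3.

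The comparison of CD301b with SIRPa asks what sets dendritic cells sorted for CD301b apart from those sorted as SIRPa, a gate that is not described further in the sources used here. CD301b cells had higher levels of genes known to respond to IL-4 and IL-13, among them Cdh1, the adhesion protein E-cadherin, at 297 ± 38.6 against 92.9 ± 5.82 CPM, and Ccl17, a chemokine that attracts CCR4-bearing T cells, at 119 ± 11.3 against 34.3 ± 4.71 CPM. They also had more transcript of Il13ra1, a receptor chain for IL-4 and IL-13, at 188 ± 27.8 against 87.6 ± 4.54 CPM. SIRPa cells had higher levels of Ccl5, a chemokine of mature dendritic cells, at 258 ± 12.0 against 69.7 ± 13.5 CPM, and of Irf8 and Id2. These transcription factors stood, for Irf8, at 356 ± 49.4 against 174 ± 29.5 CPM and, for Id2, at 133 ± 2.22 against 71.6 ± 1.17 CPM. Of 15417 genes tested, 339 were higher in CD301b and 321 lower, 660 in all, of which 100 and 130 differed by at least 2-fold. Without SIRPa replicate 1 the count was 328, without SIRPa replicate 3 it was 418 and without CD301b replicate 3 it was 438.

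Among the IL-4 and IL-13 response genes, 10 of 29 tested were higher in CD301b, 3 were lower and 16 did not pass, and adjusted over the list alone 12 were higher and 3 lower. With 1 library left out, 5 to 12 were higher and 0 to 3 lower, with 6 and 0 without CD301b replicate 1 or SIRPa replicate 1, 6 and 2 without CD301b replicate 3 or SIRPa replicate 2, and 5 and 1 without SIRPa replicate 3. Among the lower genes, Fcer2a, the IgE receptor CD23, had 2 counts in CD301b and 223 in SIRPa, a ratio of 119 between SIRPa and CD301b (95% interval 32.5 to 987). Its call (adjusted p = 0.0285) was lost without CD301b replicate 1 or 4 or SIRPa replicate 1 or 3 (0.0640 to 0.167). Cdh1 (chromosome 8, 106603351 to 106670246) was higher by 1.68 ± 0.15 on the log2 scale (adjusted p = 5.15e-07), Flt1, a VEGF receptor, by 2.07 ± 0.19 (1.47e-06), and Ccl17 (chromosome 8, 94810453 to 94812036) by 1.79 ± 0.18 (2.84e-06). Ccl22, the companion ligand of CCR4, stood at 903 ± 25.4 CPM in CD301b and 838 ± 26.2 in SIRPa (adjusted p = 0.754). As a set the list was higher in CD301b, with a median log2 fold change of 0.58 (camera, adjusted p = 1.08e-09), and adjusted p = 0.0409 with an estimated correlation. In this comparison 11 of 26 lists passed with the preset correlation, 1 with an estimated correlation, which was this list, and 8 with fry. Of the 29 tested IL-4 and IL-13 response genes, 12 also stand in another list. Irf4, Klf4 and Clec10a belong to cDC2 identity too, and Ccl17 to the mature DC programme, so the results of these lists are not separate.

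**Figure D2:**
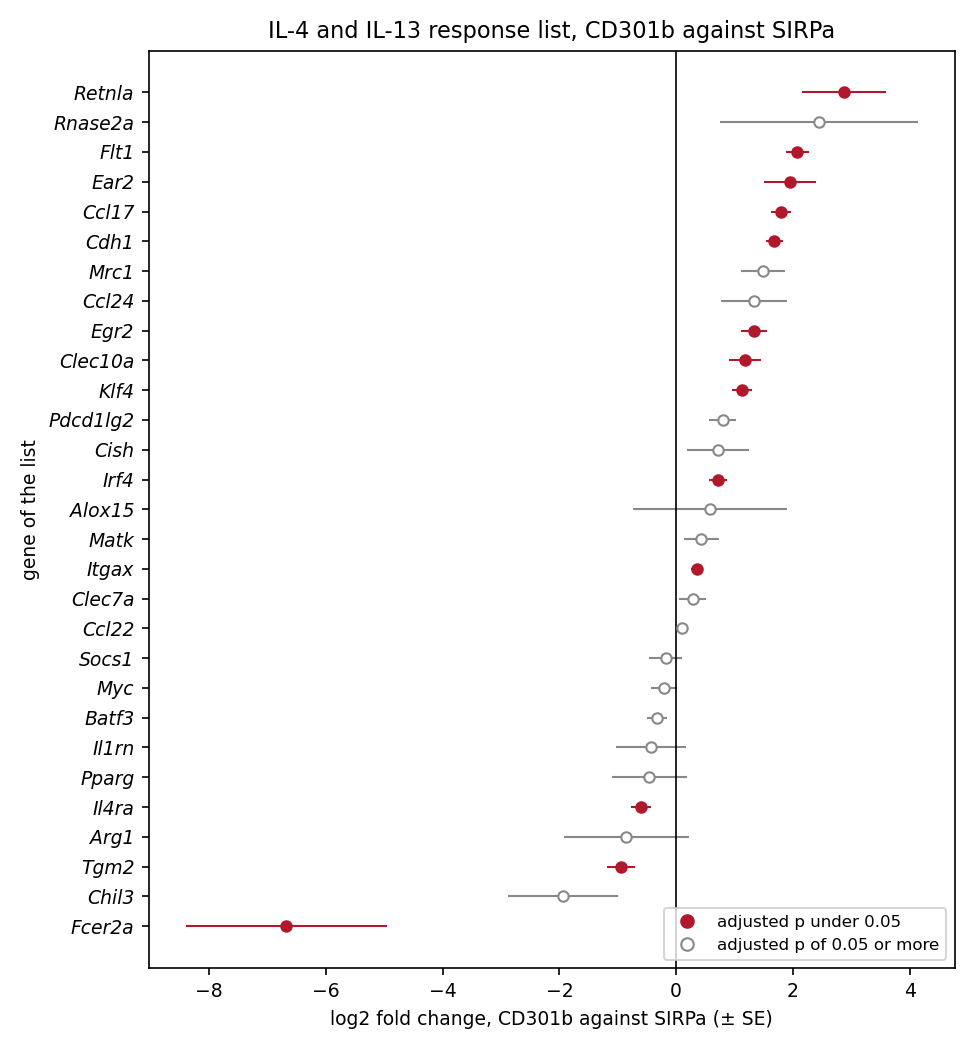
Log2 fold change of the tested IL-4 and IL-13 response genes between CD301b and SIRPa libraries (x axis, points with SE bars, n = 3 libraries each), filled where the adjusted p passed the threshold. Of 29 genes, 10 lie to the right with a call and 3 to the left, and the fitted value of Fcer2a rests on very few CD301b counts.

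The receptor chains and the signal transducer of IL-4 and IL-13 did not move together. Il13ra1 (chromosome X, 36112110 to 36171259) was higher in CD301b by 1.10 ± 0.13 on the log2 scale (adjusted p = 1.90e-05). Il4ra (chromosome 7, 125552120 to 125579474) had a log2 fold change of -0.60 ± 0.17 (adjusted p = 0.0464), with 90.8 ± 21.6 CPM in CD301b and 138 ± 13.4 in SIRPa. That call was lost without any single one of CD301b replicate 1 or 4, SIRPa replicate 1, 2 or 3, or XCR1 replicate 1, with adjusted p from 0.0537 to 0.213. Il2rg, the common gamma chain, stood at 152 ± 11.6 CPM in CD301b and 151 ± 10.2 in SIRPa (adjusted p = 0.996), while the transcription factor Stat6 stood at 164 ± 14.0 and 148 ± 3.69 CPM (adjusted p = 0.620). The cytokine genes themselves were at the floor and not tested: Il4 had 3 counts in the SIRPa libraries and 0 in the others, and Il13 had 3 in SIRPa, 4 in XCR1 and 0 in CD301b libraries. Of Il2rg's 2387 exonic bases, 728 are shared with Gm20489 on the same strand, and 571 of the 6002 of Il4ra lie opposite Gm44876, so reads of these genes are uncertain.

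In the MHC class II presentation list, 7 of 14 genes were higher in CD301b, 1 was lower and 6 did not pass, and adjusted over the list alone 10 were higher and 3 lower. H2-DMa and H2-DMb1, which form the chaperone that loads peptides on class II, were higher by 0.91 ± 0.10 (adjusted p = 1.27e-05) and 0.70 ± 0.11 (0.000506) on the log2 scale. The lysosomal protease Lgmn was the lower gene, with -0.70 ± 0.11 (0.000449). The set test gave adjusted p = 1.50e-07 and adjusted p = 0.203 with an estimated correlation. Of 17 MHC class I presentation genes, 1 was higher and 1 lower, 15 did not pass (set adjusted p = 0.359), and adjusted over the list alone 1 was higher and 3 lower. The higher gene, Pdia3, a chaperone (0.33 ± 0.09, 0.0418), did not pass in 7 of 9 fits that left out 1 library (0.0538 to 0.201), and the lower, H2-K1 (-0.38 ± 0.10, 0.0356), not in 5 of 9 (0.0572 to 0.173). Neither passed without CD301b replicate 3 or 4 or SIRPa replicate 1, 2 or 3.

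Genes of the mature DC programme, which dendritic cells switch on as they leave the tissue-resident state, were lower in CD301b as a set (median -0.30, adjusted p = 2.96e-08, and adjusted p = 0.211 with an estimated correlation). Of 36 tested, 10 were lower, 1, Ccl17, was higher and 25 did not pass, and adjusted over the list alone 17 were lower and 3 higher. The lower genes numbered 5 without SIRPa replicate 1 and 6 without CD301b replicate 3. Ccl5 had a log2 fold change of -1.89 ± 0.13 (adjusted p = 1.22e-08) and Cacnb3, a calcium channel subunit, -0.83 ± 0.11 (5.98e-05). The cDC1 identity list split, with 8 of 20 genes lower in CD301b, 5 higher and 7 not passing, and adjusted over the list alone 10 lower and 6 higher (set adjusted p = 4.71e-05, and adjusted p = 0.203 with an estimated correlation). The higher ones numbered 2 without CD301b replicate 3 or SIRPa replicate 1, and 3 without CD301b replicate 1 or SIRPa replicate 2 or 3. Irf8 had a log2 fold change of -1.03 ± 0.13 (5.73e-05), Id2 of -0.90 ± 0.11 (2.56e-05), and Cd8a stood at 117 ± 3.63 against 90.8 ± 7.97 CPM without passing (0.0703). Xcr1 itself had -4.01 ± 0.56 (0.0107), which did not pass without CD301b replicate 1 (-3.68, 0.0557) or CD301b replicate 3 (-3.85, 0.0691). Its level in SIRPa was 1.25 ± 0.677% of that in XCR1 libraries.

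Of 20 cDC2 identity genes, 5 were higher in CD301b, 1 was lower and 14 did not pass, and adjusted over the list alone 5 were higher and 2 lower. Without CD301b replicate 1 or 3 or SIRPa replicate 1 or 2, 3 were higher, and without SIRPa replicate 3, 2 were. The higher ones included the adhesion protein Epcam, by 1.76 ± 0.18 (adjusted p = 5.80e-06), and the transcription factor Klf4, by 1.13 ± 0.17 (0.000284). The lower one was the lectin Clec12a, with -0.98 ± 0.17 (0.00138). The set test pointed up (adjusted p = 0.0803) while the median and the mean were both -0.07. It passed without CD301b replicate 4 (0.0245), XCR1 replicate 1 (0.0132) or XCR1 replicate 2 (0.0446). Csf1r, a macrophage and cDC2 growth factor receptor, stood at 639 ± 54.4 and 672 ± 33.3 CPM (0.945).

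Genes for sensing microbes and for the type I interferon response were lower in CD301b by their set tests. Of 24 pattern recognition receptors, 5 were lower and 19 did not pass, and adjusted over the list alone 6 were lower and 1 higher (set adjusted p = 0.000475, and adjusted p = 0.0702 with an estimated correlation). Tlr12, a sensor of profilin, had a log2 fold change of -1.27 ± 0.18 (adjusted p = 0.000121) and Tlr3, a sensor of double-stranded RNA, -1.14 ± 0.20 (0.00133). Of these 24 genes, 4 also stand in another list, among them Tlr3 in cDC1 identity and Clec12a in cDC2 identity. The results of these lists are therefore not separate. Of 28 interferon response genes, 4 were lower and 24 did not pass, with 10 lower adjusted over the list alone (set adjusted p = 1.36e-05, and adjusted p = 0.211 with an estimated correlation). Of the 28, edgeR called 0 without SIRPa replicate 1, 2 without CD301b replicate 3 or SIRPa replicate 3, and 7 without XCR1 replicate 3. With all libraries, limma-voom called 9, DESeq2 7 and the fit on only the 6 libraries compared 8.

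Chemokine genes and T cell ligands went both ways. Of 23 chemokine and chemokine receptor genes, 2 were higher, 4 lower and 17 not passing, and adjusted over the list alone 3 were higher and 6 lower (set adjusted p = 0.345). Ccl9, a macrophage chemokine, was higher in CD301b by 1.53 ± 0.20 (adjusted p = 5.41e-05) beside Ccl17, while Ccl5 was lower. Of 23 costimulation and inhibition ligands, 2 were higher, 4 lower and 17 not passing, and adjusted over the list alone 3 were higher and 5 lower (set adjusted p = 0.396). Tnfsf9, the ligand of the costimulatory receptor 4-1BB, was higher by 2.14 ± 0.42 (0.00383), and Havcr2, an inhibitory receptor also known as TIM-3, by 0.56 ± 0.11 (0.00326). Of 19 apoptotic cell uptake genes, 3 were higher, 3 lower and 13 not passing, and adjusted over the list alone 3 were higher and 4 lower (set adjusted p = 0.921). Timd4, a receptor for phosphatidylserine on dying cells, was higher by 1.61 ± 0.28 (0.00160) and Lrp1, a scavenger receptor, by 0.66 ± 0.13 (0.00476). The counts of lower genes in these lists changed when 1 library was left out, which also leaves fewer libraries for the test. Without SIRPa replicate 1, 2 chemokine genes, 0 ligands and 0 uptake genes were lower. Without CD301b replicate 3, 0 ligands and 1 uptake gene were, and other single losses left 1 to 4 ligands and 1 to 4 uptake genes.

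The genes with the largest differences included several that belong to none of these lists. Higher in CD301b were Mgl2 at 26.9-fold (adjusted p = 1.22e-11), the scavenger receptor relative Fcrls, at 18.1 ± 5.13 against 0.843 ± 0.116 CPM (1.64e-05), and the nuclear corepressor Hr, at 93.8 ± 10.7 against 8.98 ± 1.41 CPM (1.22e-08). So were the elongation factor Tcea3, at 23.0 ± 2.33 against 2.44 ± 0.373 CPM (4.11e-05), and Pi16, at 44.4 ± 6.66 against 5.31 ± 1.09 CPM (2.57e-06). Lower were the adhesion protein Ncam1, at 0.219 ± 0.283 against 10.9 ± 2.37 CPM (0.000872), the metalloprotease Pappa2, at 0.636 ± 0.467 against 17.9 ± 7.08 CPM (1.27e-05), and Col17a1, a collagen, at 0.442 ± 0.234 against 11.5 ± 2.25 CPM (0.000431). Another of the 6 highest was Cxcr2, a neutrophil chemokine receptor, at 22.6 ± 3.70 against 1.31 ± 0.368 CPM (0.0138). The rule also took the granule protease Gzmc, at least 495-fold lower in CD301b (0.0187), where it had 0 counts. Its level in SIRPa was 21.4 ± 18.9 CPM, with 41.5, 18.8 and 3.96 CPM in replicates 1 to 3. It also took the coagulation factor F5, at 0.137 ± 0.125 against 16.8 ± 14.6 CPM (0.0196). Cxcr2 did not pass without CD301b replicate 1 or 3 or SIRPa replicate 1, 2 or 3 (0.0605 to 0.122). Gzmc did not pass without CD301b replicate 1, 3 or 4, SIRPa replicate 2 or XCR1 replicate 1 or 2 (0.0533 to 0.0774), and F5 without CD301b replicate 1, 3 or 4 or XCR1 replicate 1 (0.0533 to 0.140).

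Markers of other cell types and of handling also differed. Of 18 immediate early and dissociation genes, 4 were higher in CD301b and 14 did not pass, with 8 higher adjusted over the list alone (set adjusted p = 6.75e-08, and adjusted p = 0.0702 with an estimated correlation). They included Atf3, by 0.71 ± 0.14 (adjusted p = 0.00340), and Egr1, by 0.74 ± 0.15 (0.00555), and 2 were called without SIRPa replicate 2 and 7 without CD301b replicate 4. Of 18 macrophage genes, 4 were lower in CD301b, 1 was higher and 13 did not pass, with 6 lower and 1 higher adjusted over the list alone (set adjusted p = 3.42e-06, and adjusted p = 0.203 with an estimated correlation). Vcam1 had -1.18 ± 0.14 (1.56e-05), and Timd4 was the higher one. Without SIRPa replicate 1, 2 were lower, and without XCR1 replicate 3, 6 were. With all libraries, limma-voom called 12 of the 18, DESeq2 7 and the fit on only the 6 libraries compared 10, so the count depends on the fit. C1qa, a complement component of macrophages, stood at 401 ± 20.7 CPM in CD301b and 704 ± 34.9 in SIRPa with adjusted p = 0.698, which became 1.36e-05 without XCR1 replicate 3 and ranged from 2.16e-06 to 0.876 over the alternatives. Of 13 B cell genes, 2 were lower and 11 did not pass, with 4 lower adjusted over the list alone (set adjusted p = 0.000171, and adjusted p = 0.203 with an estimated correlation). Ms4a1, the B cell surface protein CD20, was at least 133-fold lower (4.15e-05). Fcer2a was the other, and without CD301b replicate 1 or 4 or SIRPa replicate 1 or 3, where its call was lost (0.0640 to 0.167), 1 gene was called. Without any 1 of the XCR1 libraries, 3 were. For these 13 genes limma-voom called 4, DESeq2 3 and the fit on only the 6 libraries compared 5. Of 15 monocyte genes, 1, Ly6c2, was lower by the test, at 49.1 ± 8.07 against 98.0 ± 4.58 CPM (0.00157), and 14 did not pass. Adjusted over the list alone, 2 were lower (set adjusted p = 0.251). Without XCR1 replicate 3, 2 monocyte genes were higher and 2 lower. In this list limma-voom called 5, DESeq2 2 and the fit on only the 6 libraries compared 6. Of 10 granulocyte genes, 1, Cxcr2 with the losses given above, was higher and 9 did not pass, with 1 higher and 2 lower adjusted over the list alone and a median of -3.22 (set adjusted p = 0.00749, and adjusted p = 0.560 with an estimated correlation).

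Of 16 plasmacytoid DC genes, Cd209d, a lectin, and Tcf4, the transcription factor that sets plasmacytoid identity, were higher in CD301b by 2.41 ± 0.21 (adjusted p = 3.25e-06) and 0.93 ± 0.13 (0.000122), and 14 did not pass, with 2 higher and 2 lower adjusted over the list alone, the same counts as over all genes without XCR1 replicate 2. The set test pointed up (0.335) with a median of -0.17 and a mean of -0.41. Of 33 cell cycle genes, 1 was higher and 32 did not pass, with 1 higher adjusted over the list alone (set adjusted p = 0.000879, adjusted p = 0.482 with an estimated correlation, and 0.0741 without SIRPa replicate 1). It was Cenpe, a kinesin (0.59 ± 0.14, 0.0189), not passing without CD301b replicate 1 or 4 or SIRPa replicate 1, 2 or 3 (0.0534 to 0.0897). Mki67 stood at 495 ± 56.4 and 413 ± 67.4 CPM (0.416). Of 11 cholesterol efflux genes, 1 was higher, 1 lower and 9 not passing, also adjusted over the list alone, with a median of 0.04, a mean of -0.20 and a test that pointed down (set adjusted p = 0.339, and 0.0161 without XCR1 replicate 3). The higher gene, Scd2 (0.0249), did not pass without CD301b replicate 3 or SIRPa replicate 1, 2 or 3 (0.0886 to 0.162), and the lower, Pltp (0.0455), not without any 1 of the CD301b or SIRPa libraries (0.0530 to 0.318), while 4 were lower without XCR1 replicate 3. In the cholesterol efflux list, limma-voom and the fit on only the 6 libraries compared each called 5 genes, and DESeq2 3. Of 6 stroma and endothelium genes, 1, the adhesion protein Pecam1, was higher by 1.28 ± 0.20 (0.000599) and 5 did not pass. Adjusted over the list alone, 1 was higher and 1 lower (set adjusted p = 0.426). Kdr passed as lower without CD301b replicate 1 (0.0304) or any 1 of the XCR1 libraries (0.0445 to 0.0461). In the thymic epithelium list, 1 of 10 genes was lower, also adjusted over the list alone, and 9 did not pass (set adjusted p = 0.426). It was Aire (chromosome 10, 78030022 to 78043610), which drives tissue antigens in thymic epithelium, at 1.67 ± 0.300 CPM in CD301b against 8.99 ± 0.223 in SIRPa (-2.43 ± 0.54, adjusted p = 0.0108), not passing without SIRPa replicate 1 (0.0804), 2 (0.0549) or 3 (0.0626).

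In 5 lists edgeR called 0 genes between CD301b and SIRPa, over all genes and adjusted over the list alone. For the 21 thymocyte and T cell genes, 0 had an unadjusted p under 0.05, and limma-voom called 1 and DESeq2 0 (set adjusted p = 0.579, and 0.0147 without CD301b replicate 1). For the 21 cholesterol synthesis genes, 3 had an unadjusted p under 0.05, and limma-voom and DESeq2 called 0 (set adjusted p = 0.0679, and 0.0216 without CD301b replicate 4 and 0.0486 without XCR1 replicate 1). For the 13 NK cell and innate lymphoid genes, these counts were 3, 0 and 1 (set adjusted p = 0.334). For the 11 mitochondrially encoded genes they were 1, 0 and 0 (set adjusted p = 0.569, and 0.0116 without CD301b replicate 4, where 1 gene was lower). For the 6 erythroid and platelet genes they were 0 by each (set adjusted p = 0.620), where the median was 0.11 and the mean -0.11.

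**Figure D3:**
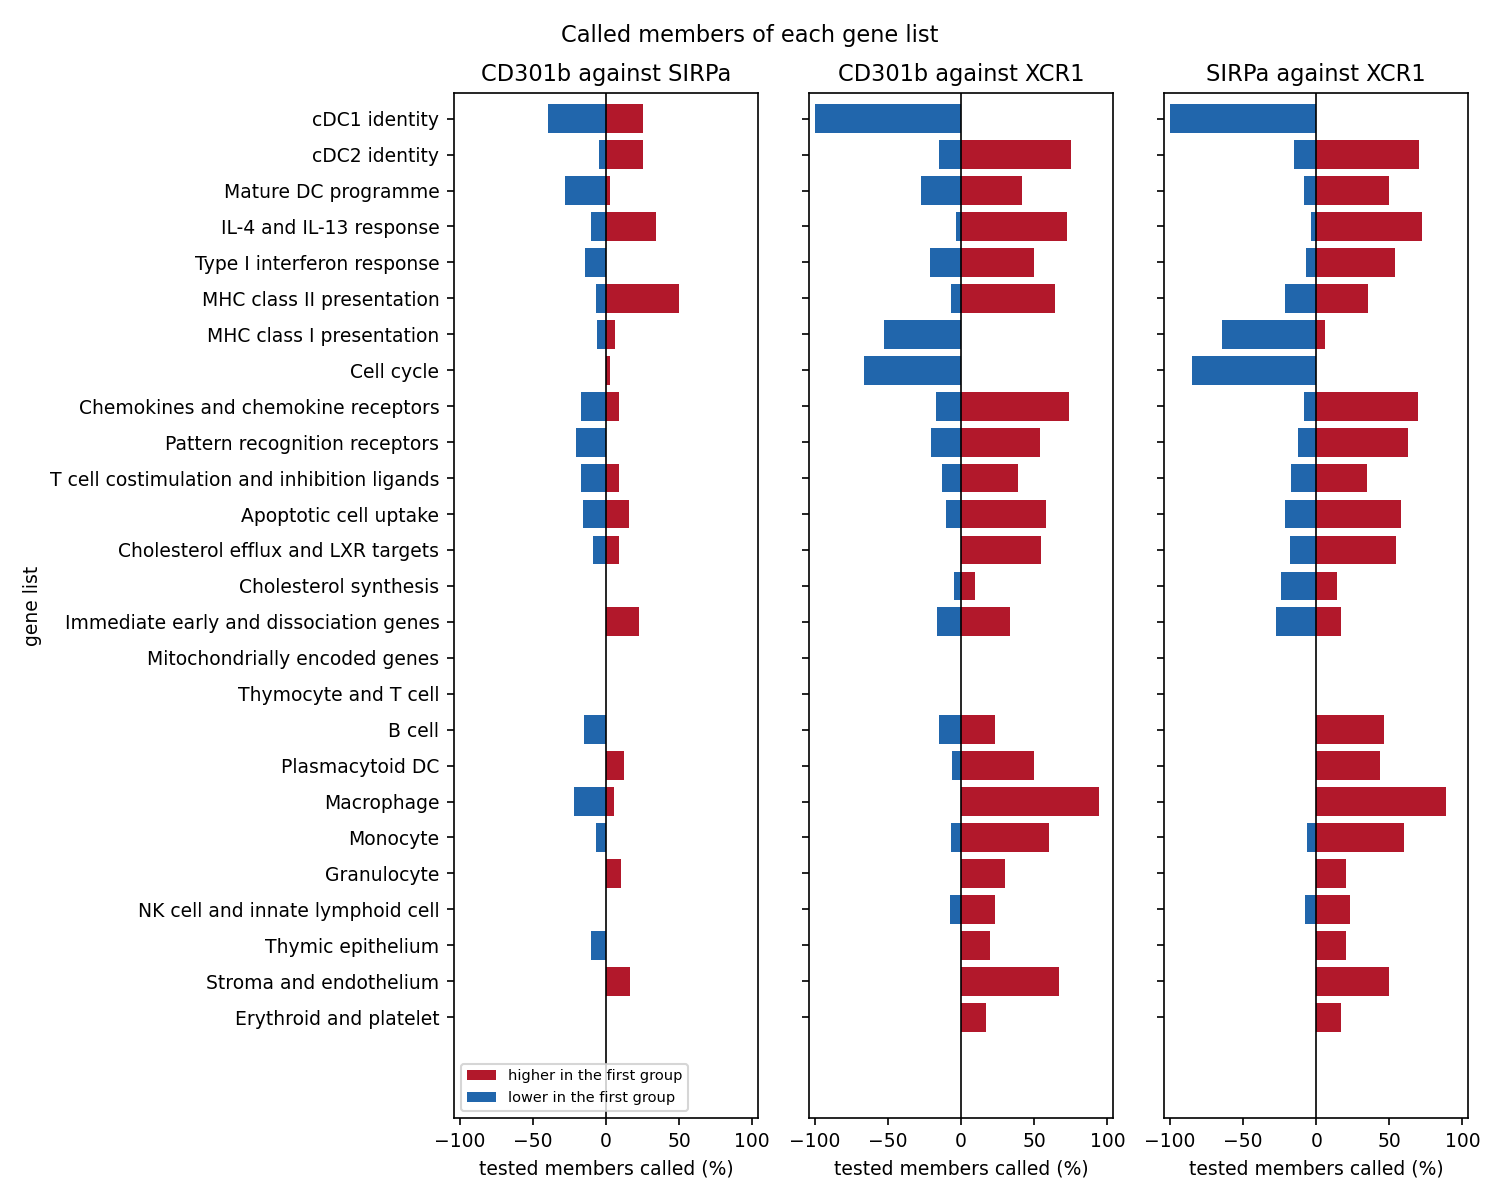
Share of the tested genes of each of the 26 gene lists (y axis) that were called higher (right, red) or lower (left, blue) in the first population named (x axis, percent), for the 3 comparisons. The IL-4 and IL-13 response list holds 10 higher and 3 lower genes between CD301b and SIRPa, and 21 higher and 1 lower in each comparison with XCR1.

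The comparison of CD301b with XCR1 sets a CD301b-bearing population against cDC1. CD301b cells had higher levels of cDC2, macrophage and monocyte genes and of IL-4 and IL-13 response genes, and XCR1 cells of every tested cDC1 gene. The transcription factor Irf4, which cDC2 depend on, stood at 252 ± 26.2 CPM in CD301b and 9.97 ± 3.21 in XCR1, and Cdh1 at 297 ± 38.6 and 7.49 ± 2.00 CPM. Clec9a, a cDC1 receptor for dead cells, stood at 8.86 ± 0.914 and 186 ± 26.3 CPM, and Ppt1, a lysosomal thioesterase, at 131 ± 8.59 and 1895 ± 116 CPM. Of 15417 genes, 2081 were higher in CD301b and 1406 lower, 3487 in all, of which 1366 and 554 differed by at least 2-fold.

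All 20 cDC1 identity genes tested were lower in CD301b, also adjusted over the list alone (set adjusted p = 6.14e-80, and 0.000627 with an estimated correlation), with log2 fold changes of -4.39 ± 0.18 for Clec9a (adjusted p = 9.59e-14) and -2.85 ± 0.11 for Id2 (8.06e-14). Of 20 cDC2 identity genes, 15 were higher, 3 lower and 2 not passing, with 15 higher and 4 lower adjusted over the list alone (set adjusted p = 8.92e-29). Irf4 was higher by 4.66 ± 0.18 (2.28e-13) and Klf4 by 2.98 ± 0.18 (7.44e-11). Xcr1 had -10.32 ± 0.57 (1.27e-05), Mgl2 was higher by 8.42 ± 0.22 (4.29e-15) and Sirpa by 5.69 ± 0.16 (3.50e-15).

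Of 29 IL-4 and IL-13 response genes, 21 were higher in CD301b, 1 was lower and 7 did not pass, also adjusted over the list alone. The median was 2.87 (set adjusted p = 2.36e-27). Of the 29, 12 also stand in other lists, among them Irf4, Klf4 and Clec10a of cDC2 identity. Cdh1 was higher by 5.31 ± 0.18 (adjusted p = 5.39e-15) and Flt1 by 3.82 ± 0.21 (1.46e-11). Of the receptor genes, Il13ra1 was higher by 1.55 ± 0.13 (1.04e-08) and Il2rg by 2.25 ± 0.15 (1.94e-10), while Il4ra stood at 90.8 ± 21.6 and 84.2 ± 16.1 CPM (0.731) and Stat6 at 164 ± 14.0 and 147 ± 5.19 CPM (0.333).

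Chemokines and scavenging genes were among those higher in CD301b. Of 23 chemokine genes, 17 were higher, 4 lower and 2 not passing, also adjusted over the list alone (set adjusted p = 3.95e-12). Ccl9 stood at 108 ± 8.95 against 0.898 ± 0.519 CPM (adjusted p = 6.53e-14). Of 19 apoptotic cell uptake genes, 11 were higher, 2 lower and 6 not passing, with 11 higher and 3 lower adjusted over the list alone (set adjusted p = 6.50e-11). Axl, a receptor tyrosine kinase that binds dying cells, stood at 519 ± 27.7 against 35.7 ± 2.64 CPM (1.53e-15) and Lrp1 at 233 ± 30.0 against 13.5 ± 1.74 CPM (3.25e-14). Of 11 cholesterol efflux genes, 6 were higher and 5 not passing, with 6 higher and 1 lower adjusted over the list alone (set adjusted p = 1.33e-08). The lipid transporter Abca1 stood at 272 ± 17.6 against 11.7 ± 6.81 CPM (9.41e-05).

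The called antigen presentation genes of the 2 classes lay mostly in opposite directions. Of 14 MHC class II genes, 9 were higher in CD301b, 1 lower and 4 not passing, with 11 higher and 1 lower adjusted over the list alone (set adjusted p = 2.12e-08, and adjusted p = 0.0935 with an estimated correlation). The protease Ctss stood at 2950 ± 253 against 680 ± 59.6 CPM (5.90e-13). Of 17 MHC class I genes, 9 were lower and 8 not passing, with 11 lower and 1 higher adjusted over the list alone (set adjusted p = 1.51e-05, and adjusted p = 0.212 with an estimated correlation). The immunoproteasome subunit Psmb9 had -1.48 ± 0.14 (3.93e-08). Of 33 cell cycle genes, 22 were lower in CD301b and 11 not passing, with 29 lower adjusted over the list alone (set adjusted p = 2.32e-08, and adjusted p = 0.171 with an estimated correlation). The proliferation marker Mki67 stood at 495 ± 56.4 against 863 ± 146 CPM (0.000217). Without XCR1 replicate 3, 15 were lower.

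Mature DC genes were divided, with 15 of 36 higher in CD301b, 10 lower and 11 not passing, also adjusted over the list alone, and a median of 0.08 and a mean of 0.02 beside a test that pointed down (set adjusted p = 0.885). Il12b, a subunit of the cytokine IL-12, stood at 11.3 ± 1.74 against 146 ± 30.6 CPM (adjusted p = 1.78e-12) and Ccl17 at 119 ± 11.3 against 12.8 ± 3.41 CPM (3.63e-11). Of 24 pattern recognition receptors, 13 were higher, 5 lower and 6 not passing, with 15 higher and 5 lower adjusted over the list alone (set adjusted p = 0.0185, and adjusted p = 0.0776 with an estimated correlation). Among the lower ones, Tlr11 had -3.77 ± 0.21 (1.36e-11) and Tlr3 -3.72 ± 0.21 (2.21e-11). Of 28 interferon response genes, 14 were higher, 6 lower and 8 not passing, with 16 higher and 6 lower adjusted over the list alone (set adjusted p = 0.000228, and adjusted p = 0.212 with an estimated correlation). Ifit3 stood at 58.2 ± 9.97 against 2.16 ± 0.973 CPM (5.32e-12).

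Several genes were not detected in 1 of the populations. Hr was at least 1932-fold higher in CD301b (adjusted p = 3.68e-14), the coagulation factor F10 at least 1015-fold (2.47e-13) and the matrix protein Spon1 at least 800-fold (4.59e-14). Fzd1, a receptor for Wnt proteins, was at least 1797-fold lower (8.82e-11), and Cxcr3, a chemokine receptor, at least 333-fold lower (1.28e-07). Of 18 macrophage genes, 17 were higher in CD301b and 1 not passing, also adjusted over the list alone (set adjusted p = 4.79e-32). Of 15 monocyte genes, 9 were higher, 1 lower and 5 not passing, with 10 higher and 1 lower adjusted over the list alone (set adjusted p = 3.45e-14). Of the macrophage list's genes, 15 lay over 1 CPM in all 3 populations. Of 21 thymocyte genes, edgeR called 0, with 0 at an unadjusted p under 0.05 and 1 each by limma-voom and DESeq2 (set adjusted p = 0.603, and 0.00177 without XCR1 replicate 3, where 6 genes were higher).

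The comparison of SIRPa with XCR1 sets the population sorted as SIRPa against cDC1. SIRPa cells had higher levels of cDC2, macrophage and chemokine genes, and XCR1 cells of every tested cDC1 gene. Irf4 stood at 154 ± 8.32 against 9.97 ± 3.21 CPM, Axl at 725 ± 65.8 against 35.7 ± 2.64 CPM, and Lyz2, the lysozyme of myeloid cells, at 2697 ± 214 against 36.4 ± 13.6 CPM. Itgae, an integrin of cDC1, stood at 49.1 ± 6.85 against 484 ± 46.4 CPM, and Cd86, a costimulatory ligand, at 114 ± 13 against 282 ± 30.0 CPM. Of 15417 genes, 2147 were higher in SIRPa and 1656 lower, 3803 in all, of which 1478 and 583 differed by at least 2-fold.

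All 20 cDC1 identity genes tested were lower in SIRPa, also adjusted over the list alone (set adjusted p = 1.31e-67), with -3.95 ± 0.17 on the log2 scale for Clec9a (adjusted p = 3.68e-13) and -3.30 ± 0.15 for Itgae (4.26e-13). Of 20 cDC2 identity genes, 14 were higher, 3 lower and 3 not passing, also adjusted over the list alone (set adjusted p = 1.03e-25). Irf4 was higher by 3.95 ± 0.18 (1.71e-12). Epcam stood at 29.3 ± 4.36 and 31.3 ± 7.01 CPM (0.795). Xcr1 had -6.31 ± 0.44 (4.55e-05), Mgl2 was higher in SIRPa by 3.67 ± 0.20 (9.09e-11) and Sirpa by 5.95 ± 0.16 (2.70e-15).

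Of 29 IL-4 and IL-13 response genes, 21 were higher in SIRPa, 1 was lower and 7 did not pass. Adjusted over the list alone, 24 were higher and 1 lower, with a median of 1.99 (set adjusted p = 7.55e-18). The overlap of 12 genes with other lists holds here as well. Cdh1 was higher by 3.63 ± 0.17 (adjusted p = 6.35e-13), and Clec10a, the paralog of Mgl2, stood at 28.5 ± 2.89 against 0.166 ± 0.246 CPM (7.87e-10). Il4ra was higher by 0.71 ± 0.17 (0.00338) and Il2rg by 2.24 ± 0.15 (2.16e-10). Stat6 stood at 148 ± 3.69 and 147 ± 5.19 CPM (0.971). Il13ra1 was higher by 0.44 ± 0.13 (0.0135), not passing without SIRPa replicate 1 or 2 or XCR1 replicate 3 (0.0532 to 0.0657).

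Of 28 interferon response genes, 15 were higher in SIRPa, 2 lower and 11 not passing, with 15 higher and 3 lower adjusted over the list alone (set adjusted p = 1.31e-08, and adjusted p = 0.0754 with an estimated correlation). Oasl2 was higher by 3.29 ± 0.15 (adjusted p = 4.26e-13) and Ifit3 by 5.16 ± 0.25 (1.81e-12), while Irf7 stood at 387 CPM in both. Of 36 mature DC genes, 18 were higher, 3 lower and 15 not passing, also adjusted over the list alone (set adjusted p = 0.0152, adjusted p = 0.512 with an estimated correlation, and 0.129 without XCR1 replicate 3), with Il12b at 18.2 ± 0.832 against 146 ± 30.6 CPM (2.97e-11) among the lower ones. Of 23 costimulation and inhibition ligands, 8 were higher, 4 lower and 11 not passing, with 9 higher and 4 lower adjusted over the list alone (set adjusted p = 0.393). Cd274, the inhibitory ligand PD-L1, was higher by 1.33 ± 0.15 (7.92e-07) and Icosl by 0.98 ± 0.11 (7.04e-07). Cd86 had -1.31 ± 0.13 (7.06e-08).

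Of 23 chemokine genes, 16 were higher in SIRPa, 2 lower and 5 not passing, also adjusted over the list alone (set adjusted p = 4.43e-14). Cxcl10, an interferon-induced chemokine, stood at 42.0 ± 9.24 against 2.34 ± 1.35 CPM (adjusted p = 1.04e-07). Of 24 pattern recognition receptors, 15 were higher, 3 lower and 6 not passing, with 16 higher and 4 lower adjusted over the list alone (set adjusted p = 0.000113). Tmem173, the adaptor STING, was higher by 1.65 ± 0.17 (2.20e-07). Tlr11 had -3.58 ± 0.21 (2.85e-11). Of 33 cell cycle genes, 28 were lower in SIRPa and 5 not passing, with 29 lower adjusted over the list alone (set adjusted p = 1.09e-12, and adjusted p = 0.0754 with an estimated correlation). The kinase Cdk1 had -1.68 ± 0.19 (6.17e-07). Of 14 MHC class II genes, 5 were higher, 3 lower and 6 not passing, with 5 higher and 4 lower adjusted over the list alone, and a median of -0.05 and a mean of 0.59 beside a test that pointed up (set adjusted p = 0.00557, and adjusted p = 0.357 with an estimated correlation). Of 17 MHC class I genes, 11 were lower, 1 higher and 5 not passing, with 12 lower and 2 higher adjusted over the list alone (set adjusted p = 0.000172, and adjusted p = 0.286 with an estimated correlation).

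The largest differences included Spon1, at least 1566-fold higher in SIRPa (adjusted p = 1.46e-14), F10, at least 760-fold (4.81e-13), the proton pump subunit Atp6v0d2, at least 492-fold (8.25e-11), and the chemokine Ccl12, at least 458-fold (1.48e-10). Lower were Fzd1, at 0.682 ± 0.476 against 77.7 ± 16.9 CPM (7.64e-10), and Cd207, the lectin langerin, at 1.23 ± 1.43 against 135 ± 18.9 CPM (0.00156). Of 18 macrophage genes, 16 were higher in SIRPa and 2 not passing, with 17 higher adjusted over the list alone (set adjusted p = 4.25e-40). Of 13 B cell genes, 6 were higher and 7 not passing, with 8 higher adjusted over the list alone (set adjusted p = 0.00789, and adjusted p = 0.243 with an estimated correlation), and 3 higher without any 1 of the SIRPa libraries. Of 21 thymocyte genes, edgeR called 0, with 0 at an unadjusted p under 0.05, 1 by limma-voom and 0 by DESeq2 (set adjusted p = 0.651, and 0.00439 without XCR1 replicate 3, where 6 genes were higher). In CD301b against XCR1 and SIRPa against XCR1, 15 and 17 of 26 lists passed with the preset correlation, and 9 and 10 with an estimated correlation. In both of these comparisons the lists that passed with an estimated correlation included cDC1 and cDC2 identity, IL-4 and IL-13 response, chemokines, apoptotic cell uptake, cholesterol efflux, plasmacytoid DC, macrophage and monocyte genes, and in SIRPa against XCR1 also pattern recognition receptors.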

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

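Tests that left out the libraries highest in thymocyte genes or a library of the population not compared, or took the thymocyte level as a covariate, were chosen only after the data had been seen. Over 19 alternatives per comparison, no gene called in the reported fit was called in the opposite direction. Leaving out 1 library gave 328 to 813 genes for CD301b against SIRPa (660 with all), 2921 to 3249 for CD301b against XCR1 (3487) and 3015 to 4042 for SIRPa against XCR1 (3803). The lowest, 328, 418 and 438, came without SIRPa replicate 1, SIRPa replicate 3 and CD301b replicate 3, and the highest, 813, without XCR1 replicate 3. The other 10 alternatives gave 537 to 981, 2878 to 4134 and 3278 to 4329. DESeq2's Wald test gave the highest of each, and it called more unchanged genes than edgeR in the simulations. With an estimated correlation, 1, 9 and 10 lists passed in these comparisons in place of 11, 15 and 17. The log2 fold change of Xcr1 between CD301b and SIRPa ranged from -4.62 to -3.47 when 1 library was left out, and its call was lost at -3.68 and -3.85 without CD301b replicate 1 or 3. The cause was not tested. Over all named genes and alternatives, 5301 values stayed on their side of the threshold, 128 lost and 108 gained a call, 84 uncalled values changed sign and no called one did. Same-numbered libraries of different populations deviated together only weakly, with correlations of 0.00305 to 0.0413 over 7 pairs, all under the cutoff of 0.1. Differently numbered ones had -0.0672 to 0.0481. Of 8 libraries with a same-numbered partner, 4 correlated best with their own number. The summed thymocyte level ranked alike by number in SIRPa (736, 529 and 1007 CPM in replicates 1 to 3) and XCR1 (375, 274 and 1157 CPM). In CD301b it was 410 CPM in replicate 1, 768 in replicate 3 and 1083 in replicate 4. A shared origin of same-numbered libraries is therefore not excluded, and the reported fit takes no account of one. With the replicate block, the counts were 660, 2913 and 4034, and the thymocyte and T cell list turned its direction between CD301b and SIRPa with adjusted p = 0.000166, against 0.579 without it. In the same comparison, the lists of cholesterol synthesis and mitochondrially encoded genes passed with the block (0.00978 and 0.0285) and without the libraries highest in thymocyte genes (0.0475 and 0.0362), against 0.0679 and 0.569 in the reported fit. Depth limits genes near 3 counts over a group, such as Il4 and Il13. A fit without 1 library has fewer libraries, so a call lost there does not by itself show that a result rests on that library.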

Other observations

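All tests of explanations here were chosen only after the results were seen. S100a9, a neutrophil protein, varied between libraries of a population. It stood at 8.38, 4.13 and 20.2 CPM in SIRPa replicates 1 to 3, at 11.9 CPM in XCR1 replicate 3 and at 0.380 CPM in XCR1 replicate 2. Of 13 NK cell and innate lymphoid genes, 3 were higher in SIRPa than in XCR1 (1 without SIRPa replicate 1), 1 was lower and 9 did not pass, with Il7r, the IL-7 receptor, at 105 ± 11.2 against 10.5 ± 2.5 CPM (edgeR, adjusted p = 6.18e-12) and Klrk1, the receptor NKG2D, at 35.0 ± 9.32 against 64.6 ± 8.56 CPM (0.00160).

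Of 16 plasmacytoid DC genes, 8 were higher in CD301b than in XCR1, 1 was lower and 7 did not pass (edgeR and camera, set adjusted p = 7.43e-13), with Tcf4 at 389 ± 54.9 against 43.5 ± 5.79 CPM and Spib at 60.3 ± 11.1 against 4.31 ± 0.711 CPM. Kdr, a VEGF receptor of endothelium, stood at 141 ± 17.1 CPM in CD301b, 191 ± 18.2 in SIRPa and 43.4 ± 4.71 in XCR1 libraries.

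The complement gene C1qa and the apolipoprotein gene Apoe differed between CD301b and SIRPa without a call. Apoe stood at 1314 ± 150 against 3305 ± 387 CPM (edgeR, adjusted p = 0.187, with a range of 3.68e-09 to 0.416 over the alternatives). A spread among the XCR1 libraries, which share the fit, may account for the missing call: without XCR1 replicate 3, where C1qa was 9.93 CPM against 1.20 and 0.855 CPM in the others, the larger adjusted p of the 2 genes was 1.36e-05, within a range of 2.16e-06 to 0.876 over the alternatives of C1qa. Macrophage RNA in the SIRPa libraries could give the difference itself, and the macrophage list had a median log2 fold change of -0.71, but Timd4, a macrophage gene, went the other way by 1.61. Macrophage RNA and expression by SIRPa cells themselves cannot be told apart, since 15 of the 18 list genes tested lay over 1 CPM in every population and the gates are not given.

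SIRPa libraries held Xcr1 reads at 1.25 ± 0.677% of the XCR1 level. Reads exchanged between all libraries of a pool are argued against by Xcr1 in CD301b, at 0.0807% of the XCR1 level. This holds only if the CD301b libraries shared a pool with the SIRPa and XCR1 libraries, which was assumed and not tested. XCR1 cells, or their RNA, would bring other abundant transcripts at the same share as Xcr1. Over 3493 genes with at least 50 CPM in XCR1, the lowest mean level in SIRPa was 0.878% of the XCR1 level, for Fzd1. In single libraries, by contrast, 2 of the 3 held a gene below the share of Xcr1 by more than counting error, adjusted over the genes. In SIRPa replicates 2 and 3, Cd207 stood at 0.554% and 0.0700% of its XCR1 level beside 2.04% and 0.867% for Xcr1, and Fzd1 stood at 0.566% in replicate 2. In replicate 1, Cd207 stood at 2.11% beside 0.858% for Xcr1, and Gcsam, at 0.226%, did not pass (adjusted p = 0.0830). XCR1 cells or their RNA cannot be told apart from low expression of Xcr1 in SIRPa cells themselves, because no gene lay below in all 3 libraries and the share of Cd207 ranged from 0.0700% to 2.11% between them.

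Aire was higher in SIRPa than in CD301b. Thymic epithelial RNA cannot be told apart from expression by SIRPa cells themselves. The thymic epithelium list does not separate kinds of epithelium. Its 7 other genes with at least 1 CPM went both ways without passing (edgeR, adjusted p = 0.223 to 0.996). Their median log2 fold change was 0.026, from -1.10 for Krt8 to 2.90 for Prss16, 2 genes chosen after their values were seen, against -2.43 for Aire. Aire-expressing B cells or their RNA remain possible, with a median of -1.08 for the B cell list, and Ms4a1 at 5.76 ± 2.26 CPM in SIRPa. Ms4a1 was, however, also at 4.80 ± 2.62 CPM in XCR1, where Aire stood at 1.75 ± 0.516 CPM. Between SIRPa and XCR1, 6 of the 13 list genes were higher in SIRPa and 7 did not pass. With 6 of the 13 over 1 CPM in every population and the gates not given, B cell RNA cannot be told apart from expression by SIRPa cells themselves.

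The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split, counted as 1 of 10 in each comparison, gave 660, 3487 and 3803 genes. The highest of the other splits gave 0 in each by the same edgeR test. Each of those splits mixes both populations in each group, so the difference between populations adds to the spread within groups. The 0 therefore cannot show what chance alone would give.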
